A study of Rhodonia placenta with 9 samples.

How the data were processed

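RNA was sequenced from the brown-rot fungus Postia placenta (listed in GEO as Rhodonia placenta), dikaryotic strain MAD698-R, growing through wood wafers. Per the labels' protocols, a mycelial lawn formed on feeder strips over 2 to 3 weeks, wafers of 60 by 25 by 2.5 mm were stood on it for between 3 and 4 weeks, by which time the growing edge had climbed about 50 mm, and the scraped wafers were then cut into sections of 5 mm, starting at the front. Sections at 0-5, 15-20 and 30-35 mm behind the front were used, with 3 libraries each, so distance from the front stands for the age of decay. The labels call these early, middle late and late decay. They name the replicates as biological but do not say whether a replicate number marks the same wafer in each section, and p-values measure the spread between these libraries only.

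Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on a column, made into TruSeq RNA v2 libraries and sequenced on an Illumina HiSeq. Per the submitters' processing notes, the tools were Trimmomatic 0.30, FastQC, TopHat2 2.0.13, Cufflinks 2.2.1.0 and Cuffdiff. The genome build and the gene annotation are not given in the sources used here. Per the file headers, each library's deposited file holds, for 17173 gene models on 972 scaffolds, the Cufflinks FPKM (fragments scaled to transcript length and to the library's mapped fragments), its lower and upper bound and the coverage. Coverage, a deposited signal, had a median ratio to FPKM between 6.25 and 7.14 in the libraries and was used only as a check of the files. A second deposited table gives 1 FPKM per section from Cuffdiff. Its values were a median of 1.18, 1.51 and 1.55 times the mean of the 3 libraries at 0-5, 15-20 and 30-35 mm. Changes between sections are therefore on another scale there than in the libraries. A further 3 tables hold the authors' pairwise comparisons with p-values, q-values and log2 fold changes. The deposited log2 fold change held no number for 143, 157 and 126 models in these tables, so the direction was taken from the authors' 2 section values. Columns of the whole-series tables were matched to sections by name, and 0 were left unmatched.

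FPKM is scaled to each library's own total, so a rise in a few abundant transcripts lowers the values of the rest. Cufflinks estimates FPKM by sharing reads among overlapping models, and an exact 0 can be a failed estimate. Here 26 models were listed at 0 in the 3 libraries of a section although the authors' section table put them above 1 FPKM. Such models are described as listed at 0, with the value of each library and without a fold change. The annotation for antisense or overlapping models was not used here, and a dikaryon holds 2 nuclear types, so reads of near-identical alleles or paralogs may be split between models in an unknown way.

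The depth was read from the intervals in the deposited files. The distance from an FPKM to its upper bound equalled 2 FPKM divided by the square root of a number that lay within 0.02 of a whole number for 74.3% to 77.9% of the values under 30, and this was taken as the number of fragments. Summed over models, it came to between 15647670 and 18218226 fragments per library. At 1 FPKM the median model then held between 23.7 and 32.7 fragments, a counting error of 17.5% to 20.5%. This covers counting error only.

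Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), which understates the change of low models. The 12443 models with a mean of at least 1 FPKM over the 9 libraries entered 1 fit of all 3 sections with no covariate. A moderated F test asked whether the sections differed, and 3 contrasts compared pairs of sections, each two-sided and with Benjamini-Hochberg adjustment at 0.05. On values simulated from these libraries with 50 changed models per size, 4-fold changes were recovered in 78% of cases for 15-20 mm vs 0-5 mm, 80% for 30-35 mm vs 0-5 mm and 86% for 30-35 mm vs 15-20 mm, and 2-fold changes in 50%, 56% and 46%. False calls made up 7.10%, 2.38% and 5.14% of the calls in those comparisons. The simulation held 200 changed models, independent noise, no pairing and no shift of the median model. It gave 169, 168 and 175 calls, while the real comparisons gave 4215, 4823 and 5. As the adjusted p depends on the number of changed models, these shares are not the power of the real comparisons. Figures and the tests on neighbouring models used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

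Named models were chosen by a rule fixed before the data were examined. In each comparison it took the 2 largest rises and the 2 largest falls among models with an adjusted p under 0.05, no overlap between the 3 values of each section and a mean of at least 10 FPKM in the higher section. The files do not pair the model names with gene names or functions, so models are given by the name, protein number and scaffold position in the files, and whether a position is exonic cannot be stated. For the same reason the tests of 30 gene lists defined by words in gene descriptions, and their shares of the summed FPKM, were not run.

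Whether the replicate numbers pair the libraries was checked from the correlation, across models, of the deviations of same-numbered libraries from their section means. The correlations were 0.54, 0.61 and 0.32 between 30-35 and 15-20 mm and 0.24, 0.24 and 0.23 between 30-35 and 0-5 mm, each above the limit of 0.1. The correlations between 15-20 and 0-5 mm were 0.35, 0.28 and -0.05, and these sections were not taken as paired. A number that marked the same wafer would pair every section, so this partial pairing cannot hold for wafers as such. The 0.35 and 0.28 also lie above the values between 30-35 and 0-5 mm. Whether the numbers mark wafers is thus undecided, and the pairing used here comes from the data alone. No 2 libraries of a section were alike within counting noise, with a chi-square per model between 33.9 and 207.

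The alternatives were other pseudocounts (0.1 and 5 FPKM), other filters, scaling by the median of ratios, by the upper quartile or to the same sum, quantile normalization, the replicate number as a block, a robust prior, library weights (estimated gene by gene, because the default estimate did not converge), only the 6 libraries compared, and leaving out each library in turn. Added after seeing the data were median of ratios scaling with the block, the block with only 6 libraries, leaving out models whose zeros the section table contradicts, and limma-voom on the implied fragment numbers with and without scaling.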

Results

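Gene expression of the wood-decaying fungus Postia placenta was measured by RNA-seq in 9 libraries taken from 3 sections of colonized wood wafers. The section at 0-5 mm lay directly behind the advancing hyphal front (early decay), the section at 15-20 mm was further back (middle late decay) and the section at 30-35 mm was the oldest (late decay). Each section was represented by 3 libraries. Values are Cufflinks FPKM for 17173 gene models, and the implied depth was 15647670 to 18218226 fragments per library. The comparison of sections asked how expression differed from early to late stages of brown rot.

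The libraries separated by section along the main axis of variation, with the 0-5 mm section on one side and both later sections on the other. The first principal component held 67.5% of the variance, and the 0-5 mm libraries scored -86.4, -52.0 and -96.4 on it, against 29.3 to 57.2 for the 6 later libraries. Replicate 2 of the 0-5 mm section lay between the other 0-5 mm libraries and the later ones. Its correlation across models was 0.939 and 0.922 with replicates 1 and 3 of its section, which correlated at 0.982 with each other, and reached 0.907 with replicate 2 of the 15-20 mm section. The 100 most abundant models held 23.4% ± 0.76 (SD, n = 3) of the summed FPKM at 0-5 mm, 31.6% ± 1.34 (SD, n = 3) at 15-20 mm and 33.4% ± 2.53 (SD, n = 3) at 30-35 mm. The median model changed by -0.32 on the log2 scale from 0-5 to 15-20 mm and by -0.33 from 0-5 to 30-35 mm, but by -0.02 from 15-20 to 30-35 mm. Changes of single models are therefore given relative to the median model of the comparison, while the adjusted p beside them tests the change on the deposited scale unless scaling is named, and counts are given both for the values as deposited and after median of ratios scaling.

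**Figure D1:**
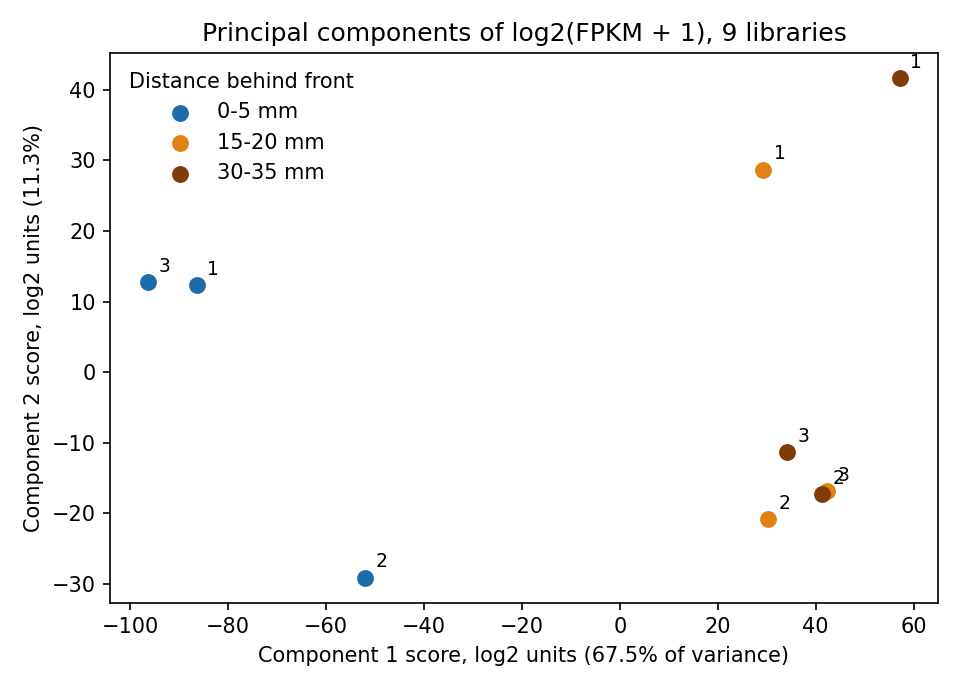
Scores of the 9 libraries on the first 2 principal components of log2(FPKM + 1), in log2 units, for the 12443 tested models; colour marks the section and the number beside a point is the replicate. The 0-5 mm libraries lie between -96.4 and -52.0 on component 1 and the later libraries between 29.3 and 57.2.

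Most models that differed among the sections had their highest mean at the hyphal front when the deposited values were used. The limma F test found 4149 of 12443 models with an adjusted p under 0.05. Of these, 3171 (76.4%) were highest at 0-5 mm, 500 at 15-20 mm and 478 at 30-35 mm. By the order of the 3 means alone, 2306 models were highest at 0-5 mm and lowest at 30-35 mm, and 865 were highest at 0-5 mm and lowest at 15-20 mm; the F test does not test the difference between the later sections. The 0-5 mm mean lay between those of the later sections in 9 models that were highest at 15-20 mm and 11 that were highest at 30-35 mm. After scaling by the median of ratios, 3190 models differed and 1588 of them (49.8%) were highest at 0-5 mm, 682 at 15-20 mm and 920 at 30-35 mm, so the excess at the front depended on the scaling. The count was 2077 without 0-5 mm replicate 1 and 2263 without 0-5 mm replicate 3, and library weights raised it to 7756.

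Between the front and the section at 15-20 mm, expression rose in some models and fell in others. The model e_gw1.272.18.1 (protein 55313, scaffold 272, positions 26864 to 28624) rose from 19.8 ± 14.3 FPKM (SD, n = 3) at 0-5 mm to 746 ± 137 FPKM (SD, n = 3) at 15-20 mm, a log2 change of 5.69 relative to the median model (SE 0.43, limma adjusted p = 0.000101). The model estExt_Genewise1.C_70204 (protein 121561, scaffold 7, positions 886954 to 889435) fell from 404 ± 296 to 3.48 ± 0.56 FPKM (SD, n = 3 each), a relative log2 change of -5.92 (SE 0.44, limma adjusted p = 6.40e-05). Scaled by the median of ratios, the limma adjusted p was 0.00014 for the first and 0.000115 for the second. Both were chosen for having no overlap between the values of the sections.

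The rule also named 2 models whose library values include exact zeros. The model estExt_fgenesh3_pm.C_1430011 (protein 107362, scaffold 143, positions 124185 to 125807) was listed at 0 in the 3 libraries at 0-5 mm and at 758, 1029 and 1122 FPKM in those at 15-20 mm. The authors' deposited section table gives it 427 FPKM at 0-5 mm and 1463 FPKM at 15-20 mm, over a wider span (121873 to 125807) that it shares with 1 other model. The model estExt_Genewise1.C_610132 (protein 122128, scaffold 61, positions 354388 to 355419) stood at 51.5, 136 and 44.6 FPKM at 0-5 mm and was listed at 0 in the later libraries. Here the authors' deposited section table goes the other way, from 92.3 FPKM at 0-5 mm to 206 FPKM at 15-20 mm, over a span (352493 to 355419) shared with 1 other model. The direction of this model is therefore uncertain.

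In all, 4215 models changed between 15-20 and 0-5 mm by limma (adjusted p under 0.05), 987 higher and 3228 lower at 15-20 mm. Of these, 335 models were at least 4-fold higher and 402 at least 4-fold lower. After median of ratios scaling 2992 models changed, 1536 higher and 1456 lower, and of at least 4-fold 429 higher and 271 lower, so the excess of lower models depended on the scaling. On the deposited scale the values of the sections did not overlap in 6642 tested models (53.4%). Chance gives 10% only where the libraries as a whole do not shift, and the median model shifted by -0.32. This share was not computed after scaling. The count of changed models was 2104 without 0-5 mm replicate 1 and 2237 without 0-5 mm replicate 3. It was 2640 without 15-20 mm replicate 2 and 2299 without 15-20 mm replicate 3, and library weights raised it to 7701.

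**Figure D2:**
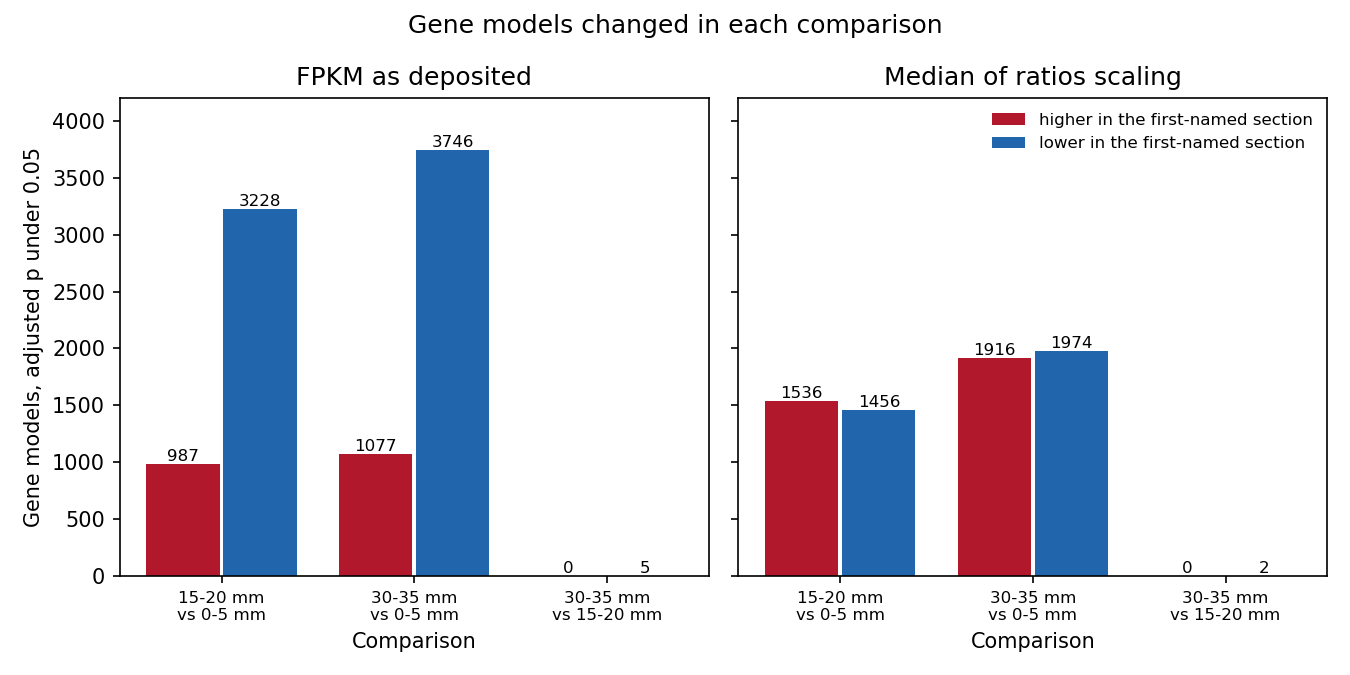
Number of gene models with a limma adjusted p under 0.05 in each of the 3 comparisons, higher (red) or lower (blue) in the section named first, for FPKM as deposited (left) and after median of ratios scaling (right). As deposited, 987 models were higher and 3228 lower at 15-20 mm than at 0-5 mm, against 1536 and 1456 after scaling.

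The section at 30-35 mm differed from the front by similarly large changes, and most models called in one later section were called in the other. The model estExt_Genewise1Plus.C_1070028 (protein 112658, scaffold 107, positions 150112 to 151468) rose from 125 ± 62.8 FPKM (SD, n = 3) at 0-5 mm to 7026 ± 2621 FPKM (SD, n = 3) at 30-35 mm, a relative log2 change of 6.17 (SE 0.51, limma adjusted p = 8.14e-05). The model estExt_Genewise1Plus.C_1750027 (protein 111730, scaffold 175, positions 103656 to 105770) fell from 279 ± 135 to 0.57 ± 0.35 FPKM (SD, n = 3 each), a relative log2 change of -7.05 (SE 0.41, limma adjusted p = 9.39e-06). The model fgenesh3_pg.1871__2 (protein 94407, scaffold 1871, positions 3316 to 3902) fell from 1244 ± 674 to 6.35 ± 1.13 FPKM (SD, n = 3 each), a relative log2 change of -6.88 (SE 0.49, limma adjusted p = 3.15e-05). Their limma adjusted p after median of ratios scaling was 0.00013, 2.01e-05 and 5.61e-05 in the same order. The fourth model named by the rule was again estExt_fgenesh3_pm.C_1430011, listed at 0 at 0-5 mm and at 1000, 1422 and 1273 FPKM at 30-35 mm, where the authors' deposited section table gives 427 and 1900 FPKM.

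The model estExt_Genewise1.C_650017 (protein 121191, scaffold 65, positions 75254 to 76589) was chosen after its values were seen. It rose from 223 ± 112 FPKM (SD, n = 3) at 0-5 mm to 3694 ± 1527 FPKM (SD, n = 3) at 15-20 mm and 8105 ± 1752 FPKM (SD, n = 3) at 30-35 mm, relative log2 changes from the front of 4.40 (SE 0.43, limma adjusted p = 0.000295) and 5.60 (SE 0.43, limma adjusted p = 5.92e-05); after median of ratios scaling the limma adjusted p was 0.000357 and 0.000104. By mean FPKM it ranked 4 and estExt_Genewise1Plus.C_1070028 ranked 5 among the models at 30-35 mm. In the authors' deposited section table both are listed at 0 FPKM at 30-35 mm with the status HIDATA, which Cuffdiff gives to loci holding too many fragments to process. The authors' deposited section table gives them 5612 and 5046 FPKM at 15-20 mm. Its values there were a median of 1.51 times the library means, so they are not on the scale of the libraries. The single libraries at 30-35 mm list 6084 to 9198 FPKM and 4157 to 9296 FPKM.

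In all, 4823 models changed between 30-35 and 0-5 mm by limma (adjusted p under 0.05), 1077 higher and 3746 lower at 30-35 mm. Of at least 4-fold, 332 were higher and 604 lower. This fit did not use the pairing. With the replicate number as a block and only the 6 libraries compared, 4195 models changed, 1096 higher and 3099 lower. That setting was chosen after the data were seen. After median of ratios scaling 3890 models changed, 1916 higher and 1974 lower, and of at least 4-fold 456 higher and 377 lower. On the deposited scale the values of the sections did not overlap in 5982 tested models (48.1%). Chance gives 10% only for libraries that are not paired and do not shift as a whole. These were taken as paired, and the median model shifted by -0.33. Of the calls against the front, 831 models were higher and 2935 lower in both later sections, and 0 were called in opposite directions. Independent lists of these sizes would share 85.4 and 972 models. After median of ratios scaling 1344 models were higher and 1337 lower in both, again with 0 in opposite directions, where independent lists would share 237 and 231. On the deposited scale, simulated unchanged groups compared with a common simulated 0-5 mm group shared 0 calls. Independent lists would share 0 there as well, so this count gives no baseline for the overlap. Across models the log2 changes of the 2 comparisons correlated at r = 0.954 with a covariance of 0.994, against r = 0.499 and a covariance of 0.0605 in the simulation, a covariance difference of 0.934. Part of the overlap may come from the shared 0-5 mm libraries, which are too few to split. The count was 2969 without 0-5 mm replicate 1 and 3120 without 0-5 mm replicate 3, and library weights raised it to 7355.

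**Figure D3:**
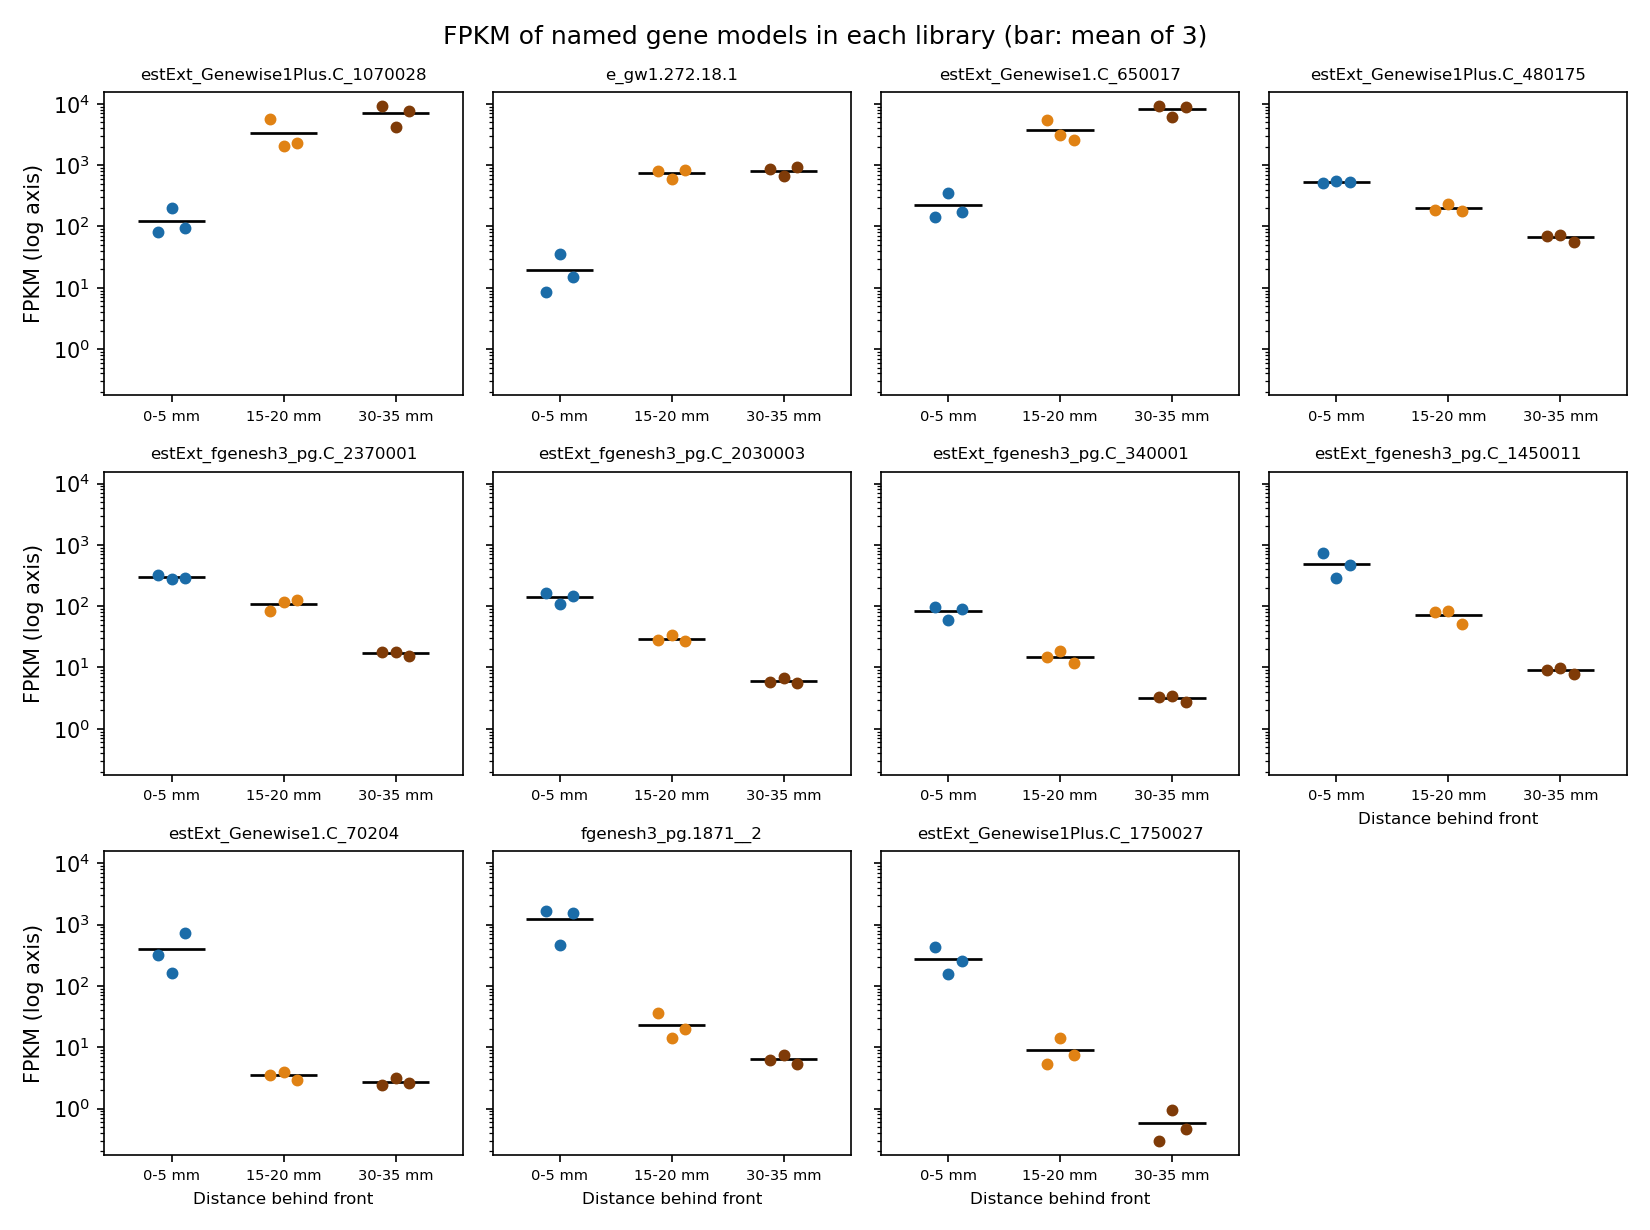
FPKM, on a log axis, of 11 named gene models in each of the 9 libraries; points are libraries, coloured by section, and black bars are means of 3. For example, estExt_Genewise1Plus.C_1070028 lies between 81.7 and 197 FPKM at 0-5 mm and between 4157 and 9296 FPKM at 30-35 mm, while estExt_fgenesh3_pg.C_2370001 falls at both steps.

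Between the 2 later sections few models were called, which does not show that few changed. The 5 that passed the test without the pairing were all lower at 30-35 mm. The model estExt_fgenesh3_pg.C_2370001 (protein 127156, scaffold 237, positions 3 to 1238) stood at 108 ± 23.0 FPKM (SD, n = 3) at 15-20 mm and at 17.1 ± 1.22 FPKM (SD, n = 3) at 30-35 mm, a relative log2 change of -2.55 (SE 0.21, limma adjusted p = 0.00438). The model estExt_fgenesh3_pg.C_1450011 (protein 127898, scaffold 145, positions 55211 to 57031) stood at 71.9 ± 18.2 and 8.98 ± 1.06 FPKM (SD, n = 3 each), a relative log2 change of -2.82 (SE 0.34, limma adjusted p = 0.0465). The remaining 3 calls fell outside the rule and were chosen after their values were seen. They were estExt_fgenesh3_pg.C_2030003 (protein 130130, scaffold 203, positions 37287 to 40003), estExt_fgenesh3_pg.C_340001 (protein 128395, scaffold 34, positions 2245 to 3629) and estExt_Genewise1Plus.C_480175 (protein 109236, scaffold 48, positions 420906 to 423280). Their relative log2 changes were -2.07 (SE 0.20, limma adjusted p = 0.0118), -1.89 (SE 0.24, limma adjusted p = 0.0473) and -1.56 (SE 0.20, limma adjusted p = 0.0473). After median of ratios scaling the limma adjusted p was 0.00827 for estExt_fgenesh3_pg.C_2370001 and 0.0123 for estExt_fgenesh3_pg.C_2030003, and 0.0575, 0.0644 and 0.135 for estExt_fgenesh3_pg.C_1450011, estExt_fgenesh3_pg.C_340001 and estExt_Genewise1Plus.C_480175, which were then not called. All 5 models also fell from 0-5 to 15-20 mm, by limma adjusted p values between 0.000173 and 0.00124, so that estExt_fgenesh3_pg.C_1450011, for example, went from 496 ± 224 FPKM (SD, n = 3) at the front through 71.9 to 8.98 FPKM.

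Between 30-35 and 15-20 mm, 466 models had an unadjusted limma p under 0.05 without the pairing. With the replicate number as a block it was 628 over all 9 libraries and 1066 with only the 6 libraries compared. If no model changed, a share of 0.05 of the 12443 tested models would pass. The 466 lie below that number, the 628 close to it and the 1066 above it. The section values did not overlap in 1019 tested models (8.19%, where chance gives 10% for libraries that are not paired). The replicate numbers were taken to pair these libraries, from the correlations of deviations alone. With the replicate number as a block over all 9 libraries only estExt_fgenesh3_pg.C_2370001 was called (limma adjusted p = 0.0313). The limma adjusted p of the other 4 models rose to between 0.0592 and 0.0766. That block also covers 15-20 and 0-5 mm, which were not taken as paired, although numbers that mark the same wafer would pair them too. With the block and only the 6 libraries compared, chosen after the data were seen, 9 models were called, 1 higher and 8 lower at 30-35 mm. Of the 5 models 4 were among them, at limma adjusted p values of 0.0408 for estExt_fgenesh3_pg.C_2370001, 0.0275 for estExt_fgenesh3_pg.C_1450011, 0.0345 for estExt_fgenesh3_pg.C_2030003 and 0.04996 for estExt_fgenesh3_pg.C_340001, while estExt_Genewise1Plus.C_480175 was not (0.0806). The limma count was 2 after median of ratios scaling, and leaving out single libraries gave 0 without 15-20 mm replicate 2 (292 models at an unadjusted p under 0.05), 1 without 15-20 mm replicate 1 or 3 or 30-35 mm replicate 1, 2 without 0-5 mm replicate 3 or 30-35 mm replicate 3, and 3 without 0-5 mm replicate 1 or 30-35 mm replicate 2. Of the 3 calls without 30-35 mm replicate 2, 1 was higher at 30-35 mm.

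The authors' deposited tables, made from the same libraries with Cuffdiff, flag 4200 models as significant between 15-20 and 0-5 mm (2041 higher and 2159 lower at 15-20 mm) and 4839 between 30-35 and 0-5 mm (2383 higher and 2456 lower at 30-35 mm). Of the limma calls on the deposited scale, 2827 of 4215 and 3228 of 4823 were also significant in the authors' deposited tables, with 0 in opposite directions. Among the calls after median of ratios scaling it was 2701 of 2992 (1374 higher and 1327 lower) and 3433 of 3890 (1651 higher and 1782 lower). Between 30-35 and 15-20 mm the authors' deposited table flags 612 models, 263 higher and 349 lower at 30-35 mm, and 57 of them differ by at least 4-fold. The 5 limma calls are among them, and 194 of the 349 lower models in the authors' deposited table had an unadjusted limma p under 0.05. Over all 12443 tested models, in both directions, it was 466. The matching number for the 263 higher models was not computed.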

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

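The tests with median of ratios scaling plus the block, the block with only 6 libraries, voom on implied fragment numbers and the removal of contradicted zeros, and the scaled versions of the overlaps and of the section order, were chosen after the data were seen; the others were fixed before the data were examined. The 13 values of named models not listed at 0 kept their sign under all 26 alternatives, and the 8 against 0-5 mm also stayed past the threshold. Of 338 such values 278 kept their call and 60 lost it, all 60 in the 5 models called between 30-35 and 15-20 mm. Over the alternatives the adjusted p ranged from 0.00109 to 0.0718 for estExt_fgenesh3_pg.C_2370001, which lost its call without 15-20 mm replicate 2 and with scaling and block together, and reached 0.417 for estExt_Genewise1Plus.C_480175.

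Leaving out single libraries gave 2077 to 4660 models differing among sections, 2104 to 4939 for 15-20 mm vs 0-5 mm, 2969 to 5383 for 30-35 mm vs 0-5 mm and 0 to 4 for 30-35 mm vs 15-20 mm. The upper ends for the first 3 came without 0-5 mm replicate 2. Array weights gave 7756, 7701 and 7355 models in the first 3 results. A minimum of 2-fold left 2497 and 2970 models in the comparisons with 0-5 mm, and a minimum of 4-fold 737 and 936. For 30-35 mm vs 15-20 mm a pseudocount of 5 FPKM, no filter on low values, median of ratios scaling, quantile normalization and a robust prior each gave 2 calls; only the 6 libraries compared, voom with scaling and a minimum of 4-fold each gave 3. Apart from the size limits, which remove models by construction, the cause was not tested. The overlap of the comparisons with 0-5 mm was 2226 of 3766 at 2-fold. The overlap with the authors' calls was 663, 785 and 3 where both sides were at least 4-fold, and 2 for 30-35 mm vs 15-20 mm after scaling. Models highest at 0-5 mm numbered 1476 of 1998 at an F adjusted p under 0.01 and 1588 of 3190 after scaling.

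With the replicate block, 30-35 mm vs 15-20 mm gave 1 call, 9 with only the 6 libraries compared, and 0 together with median of ratios scaling (limma, 708 models at an unadjusted p under 0.05). The block gave 5520 calls for 30-35 mm vs 0-5 mm, 4959 for 15-20 mm vs 0-5 mm and 4896 in the F test, within 1.5 times the main counts, and changed no other call of a named model. Between 15-20 and 0-5 mm, replicates 1 and 2 but not 3 correlated best with their own number. The planned gene list tests and list shares, and their alternatives, were not run because the files do not pair models with descriptions. At 1 FPKM the counting error of 17.5% to 20.5% limits what can be seen in low models.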

Other observations

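The tests in this part were chosen after the results were seen, except those of neighbours of unequal length and of models left out in both directions, which were fixed before their results were seen. The most abundant transcripts turned over between the front and the older wood. Of the 100 models with the highest mean FPKM at 15-20 mm, 26 were also among the top 100 at 0-5 mm, and 72 were called higher and 4 lower than at 0-5 mm, 61 and 2 of them by at least 4-fold. Of the top 100 at 30-35 mm, 23 were shared with 0-5 mm and 87 with 15-20 mm. Of the top 100 at 0-5 mm, 69 were called lower at 30-35 mm and 6 higher. As each top 100 was chosen for high values in its own section, an excess of calls in that direction is partly built in. Of all 12443 tested models, 987 were called higher and 3228 lower at 15-20 mm than at 0-5 mm. At 30-35 mm it was 1077 and 3746. The 424 models at least 4-fold higher at 15-20 mm than at 0-5 mm, relative to the median, had a median change of -0.10 from 15-20 to 30-35 mm relative to all models (two-sided exact permutation p = 0.7 for the set mean, where the smallest possible is 0.1), and its mean changed by 0.17, -0.01 and -0.48 in the same-numbered pairs (sign-flip p = 0.75). For the 276 models at least 4-fold lower it was -0.17, with 72.5% of them lower again (exact permutation p = 0.2), and the mean was lower in each same-numbered pair, by -0.27, -0.30 and -0.26 (sign-flip p = 0.25, the smallest that 3 pairs can give, so the design cannot reach 0.05).

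Models that changed against the front were grouped along the scaffolds. Runs of at least 3 neighbouring tested models, each called and at least 2-fold changed in the same direction relative to the median, numbered 44 for 15-20 mm vs 0-5 mm (20 higher, 24 lower) and 57 for 30-35 mm vs 0-5 mm (20 higher, 37 lower). Shuffled positions gave means of 10.8 and 18.02 and at most 24 and 29 runs (1000 shuffles, permutation p = 0.001, the smallest they can give). The longest run covered 8 models on scaffold 133 (107299 to 156802), lower at 30-35 mm with log2 changes, here on the deposited scale, from -1.34 to -5.34. On scaffold 9, runs of 6 models (557974 to 591743) and 5 models (598064 to 612610) lay near each other and were lower in both later sections, with median log2 changes at 30-35 mm of -3.08 and -2.60. Other runs of at least 5 models lower at 30-35 mm lay on scaffolds 21 (236617 to 245852), 75 (88779 to 105206) and 136 (112012 to 132216), and 5 models on scaffold 62 (31783 to 52457) were higher, with a median log2 change of 1.54.

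Neighbouring models changed together more than chance gives: for 30-35 mm vs 0-5 mm, changes of neighbours under 2000 bases apart correlated across models at r = 0.163, above the highest of 1000 shuffles, 0.0445. Reads shared by abutting models do not account for the whole, since neighbours 1000 to 2000 bases apart still correlated at r = 0.164 (highest shuffle 0.0684). Near-identical copies of similar length side by side do not either, since neighbours whose lengths differ by more than 1.5 times correlated at r = 0.127 (highest shuffle 0.0507). Sequences were not compared, so partial copies of unequal length that share reads stay open. At 5000 to 20000 bases apart r was 0.01, within the range of the shuffles. A candidate explanation that stays open and untested is shared regulation of neighbouring genes by the stage of decay.

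The median model was lower in the later sections, and the tables do not decide whether a few abundant models taking a larger share is the whole reason. With the 335 models called at least 4-fold higher at 15-20 mm, chosen for rising (3.96% ± 2.18 of the summed FPKM at 0-5 mm and 30.7% ± 1.03 at 15-20 mm, SD, n = 3 each), and the 402 at least 4-fold lower left out and the rest rescaled to one sum, the median change of the rest moved from -0.31 to -0.05, within the limit of 0.1 to either side of 0. For 30-35 mm, with 936 models left out, it moved from -0.31 to -0.127, between -0.20 and -0.07 when single libraries were left out, which straddles the limit; leaving out only the higher models, which by itself favours a rise of the rest, had first given 0.0925 and 0.086. The mean implied fragments of the later sections differed from 0-5 mm by -2.34% and -4.06%. FPKM is already scaled to each library's mapped fragments, so this difference does not test lower depth as a reason. Less RNA of most genes per cell could give the shift of -0.330 at 30-35 mm as well. It cannot be told apart from a larger share of a few abundant models, because FPKM carries no absolute scale.

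Replicate 2 of the 0-5 mm section lay between the other 0-5 mm libraries and the later sections. RNA of the later sections mixed into it is argued against by unequal shares: 66 models at least 16-fold higher in the other 0-5 mm libraries than in the later ones implied a median mixed share of 65.7% (quartiles 39.8% and 82.2%), and 53 models at least 16-fold higher in the later libraries 6.93% (quartiles 3.42% and 12.03%), a difference of 58.7 percentage points. Both sets were chosen on the other libraries, which may raise both shares. Wood between the 0-5 and 15-20 mm sections was not sequenced, so mixing from there was not tested. An exchanged label is argued against by the correlations of replicate 2 with its own section. The lowest of these, 0.922, is above its highest with a later library, 0.907. Its deviation correlated across models with that of replicate 2 at 15-20 mm (0.281) and 30-35 mm (0.238). A wafer or handling shared by a replicate number would give this. The labels do not state such sharing, and replicate 3 gave -0.05 between 15-20 and 0-5 mm. A front that had decayed the wood further in that wafer stays open and was not tested.

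Chance was tested with other splits of the libraries. In the F test 3 of 100 splits, the real one included, gave as many models as the real 4149, and the highest other split gave 5243. Both of these other splits kept the 3 libraries at 0-5 mm together and mixed the later ones. No split that parted the 0-5 mm libraries gave more than 2 models. The F result thus follows the contrast of the front with the later libraries. For that contrast the 3 of 100 is how often a split kept the 0-5 mm libraries together. These splits ignore the replicate numbers, so they do not exclude chance for libraries paired by number. Of all 36 splits with 1 library of each replicate number in each group, 2 gave as many, the real one included (share 0.0556), and both were among the 4 that keep the 0-5 mm libraries together, while no other of the 36 gave more than 1 model. As 4 of these 36 hold the contrast with the front by design, they are too few for a share under 0.05 on it. For pairs of sections, 10 splits are too few for a share under 0.05. The real value was the only 1 of the 10 as large in each, with 4215 against 0 for the highest other split, 4823 against 1, and 5 against 1. Among the splits that part all 3 same-numbered pairs, the highest other value was 1 for 30-35 mm vs 0-5 mm and 0 for 30-35 mm vs 15-20 mm, and the rest of the splits, which keep some pairs together, gave at most 1 each.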
